A study of Arabidopsis thaliana with 12 samples.

How the data were processed

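Small RNA was sequenced from whole Arabidopsis seedlings grown for 5 days on plates in constant light, in 12 libraries of 4 genotypes with 3 biological replicates each. Per the labels' protocols, total RNA was treated with DNase and made into libraries with the NEBNext Small RNA kit, and mutant seedlings were picked from segregating plates. The genotypes combine presence or absence of VARICOSE (VCS), a scaffold of the mRNA decapping complex, and of SUPPRESSOR OF VARICOSE (SOV), a cytoplasmic exonuclease that degrades RNA from its 3′ end. The Col-0 accession carries an inactive SOV allele, so Col-0 is the genotype with VCS and without SOV. Lines called SOV here carry the allele of the Ler accession; the labels do not say whether as a transgene or as an introgressed segment.

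Per the submitters' processing notes, the authors checked reads with FastQC, trimmed them with cutadapt 1.8.3, aligned them to TAIR10 with Bowtie 1.1.2 and compared groups with DESeq2. Alignment settings, the counting rule and the treatment of reads with several genomic positions are not stated. The deposited table holds 57544 gene strands (28772 genes, sense and antisense), each with reads of 21, 22, 23 and 24 nt. Its 48 value columns hold the deposited signal, which per the file headers belongs to 1 library and 1 read length. From the values, this signal is a read count divided by a size factor of that library and length. With a tolerance of 0.001, 100% of the values came out as whole reads, and the size factors ran from 0.597 to 4.50. Per the file headers, the authors also gave a log2 fold change, and their standard error and Wald statistic are scores from DESeq2. Per the file headers, their p-value columns are unadjusted and adjusted, per comparison and length.

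A feature below is 1 strand of 1 gene at 1 read length, and its level is the deposited normalised read count. The annotation classes are those of the table: 27588 nuclear genes other than the classes that follow, 631 tRNA genes, 178 MIR genes, 8 TAS loci (sources of trans-acting siRNAs), 88 chloroplast and 122 mitochondrial genes, and small sets of rRNA, snoRNA and snRNA genes. Of the nuclear genes, 26707 are protein-coding in the reference annotation TAIR10.1, which served for symbols and for the order of genes only. It matched 28006 of the gene identifiers and left 766 unmatched. Gene strands without a read in any library numbered 5134. Reads shared between near-identical genes, such as the LHCB2 and PPR families or the MIR399 genes, cannot be assigned with certainty because the counting rule is not stated.

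The design written before the data were examined foresaw raw counts and edgeR with TMM. Because the deposited values are normalised signal, the main test became limma 3.58.1 with a mean-variance trend in R 4.3.3. It ran on log2 of the value plus a pseudocount of 1, for features with a mean of 5 or more over all libraries. Each length had 1 fit of all 12 libraries with 1 mean per group, and Benjamini-Hochberg adjustment covered all 20590 features of a comparison (7795, 4954, 3071 and 4770 of 21, 22, 23 and 24 nt). The threshold was an adjusted p of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of weakly represented features. The 7 comparisons were loss of VCS without and with SOV, loss of SOV with and without VCS, loss of both, the cross comparison of the lines lacking 1 activity each, and the interaction. The interaction is the vcs effect without SOV minus the vcs effect with SOV.

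The labels give each group replicates 1, 2 and 3 and do not say that a number marks a shared batch. Between Col-0 and the vcs sov line, deviations of same-numbered libraries from their group means correlated with 0.116, 0.101 and 0.195, each best with its own number, so for this comparison the data point to a pairing.

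Shares of reads were computed per library from the recovered reads. Groups were compared by exact, two-sided permutation tests on 60 measures with Benjamini-Hochberg adjustment. For 6 vcs against 6 VCS libraries the smallest p is 0.002165, and for 3 against 3 it is 0.1. Counts of list features cover all lengths. Gene lists were tested at 21 nt and at 22 nt with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, which asks whether a list moves 1 way without comparing it with other genes. Values are those of 21 nt unless 22 nt is named. The lists fixed before the data were examined were the TAS loci, coding genes prone to post-transcriptional gene silencing in decay mutants, PPR genes with secondary siRNAs, auxin receptors targeted by miR393, NB-LRR genes with secondary siRNAs, other miRNA targets, the mRNA decay machinery, small RNA pathway genes and 41 MIR genes. Another 20 groups were formed from words in the reference gene descriptions after the main tests and before the groups' results were seen.

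Genes were named by a fixed rule. For both vcs comparisons it takes the 10 genes per direction with the smallest adjusted p among those with an absolute log2 fold change of 1 or more and no overlap between the libraries of the groups, leaving out rRNA and tRNA. For the other comparisons and the interaction it takes 5 per direction. It also takes VCS, SOV and, as counts with 2 to 4 examples of smallest adjusted p, the members of each list and the MIR genes. Where a group had no read, the fold is a lower bound computed from 3 reads over the whole group. Where it had 1 to 3 reads, the ratio of summed reads is given with its exact 95% interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

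On simulated data modelled on the comparison of vcs without SOV at 21 nt (7406 features), limma recovered 15.1% of 93 features changed 2-fold and 100% of 90 features changed 8-fold, with 2 false calls. The edgeR test recovered 28% and 100%, with 6 false calls. In this simulation small changes were therefore mostly missed. Few of its features changed and there was no wider shift, so these rates need not hold where most features change. The false calls likewise do not test the scaling.

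Alternatives tried were edgeR 4.0.16 on the recovered reads with TMM and with DESeq2 size factors, a DESeq2 1.42.0 Wald test, values per 1e+06 counted reads of the library (library-size scaling), values recentred on the median of MIR genes, pseudocounts of 0.5 and 5, other filters and thresholds, a block for the replicate number, each library left out in turn, and the 4 libraries numbered 3 left out together. On the recovered reads, edgeR with TMM called 11440 features for vcs without SOV, 8029 for vcs with SOV, 31 for SOV with VCS, 5424 for SOV without VCS, 11880 for the double loss, 7682 for the cross comparison and 499 for the interaction. The authors' deposited fold changes and p-values entered only a count of shared calls. Shares and figures were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Lengths other than 21 to 24 nt, sequences of single reads and mRNA levels were not analysed here.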

Results

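Small RNA reads of 21 to 24 nt were counted in whole seedlings of 4 genotypes, 3 libraries each. They were Col-0, which has the decapping scaffold VCS and lacks the 3′ exonuclease SOV; the SOV line, which has both; the vcs SOV line, which lacks VCS; and the vcs sov line, which lacks both. The series asks how small RNA abundance compares with mRNA decay rates in such seedlings. Counted reads per library (in M) were 8.81, 6.49 and 5.83 in Col-0, 6.66, 7.88 and 5.94 in the SOV line, 4.18, 4.95 and 7.43 in the vcs SOV line, and 11.6, 7.42 and 5.29 in the vcs sov line. Levels are deposited normalised read counts, given as mean ± SD with n = 3 per genotype unless stated. Gene symbols stand for small RNA reads on the named strand of that gene and do not measure its mRNA.

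The mutated genes were examined first. At the VCS locus, sense 21-nt reads were few in every genotype: 5.95 ± 3.201 in the SOV line, 4.74 ± 2.03 in Col-0, 2.56 ± 1.59 in the vcs SOV line and 7.02 ± 1.88 in the vcs sov line. Neither vcs comparison changed them (log2 fold 0.51, limma adjusted p = 0.394, without SOV, and log2 fold -0.92, adjusted p = 0.135, with SOV). At the SOV locus (AT1G77680), sense 21-nt reads rose with loss of VCS, from 0.569 ± 0.514 in Col-0 (2 reads in all) to 85.7 ± 21.6 in the vcs sov line, and from 10.8 ± 8.29 in the SOV line to 299.8 ± 34.6 in the vcs SOV line (adjusted p = 3.9e-09 and 1.22e-07). They were also lower in each genotype without SOV than in its partner with SOV (adjusted p = 0.00752 with VCS and 0.00615 without). The mRNA of these genes was not analysed here, so the reads are no check of the genotypes.

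Loss of VCS was accompanied by a large rise of 21-nt and 22-nt reads from nuclear genes. They made up 3.98 ± 0.599% of 21-nt reads in Col-0 and 39.1 ± 1.43% in the vcs sov line, and 3.81 ± 0.493% in the SOV line and 18.6 ± 0.608% in the vcs SOV line. All 6 vcs libraries lay above all 6 VCS libraries (exact permutation p = 0.002165, the smallest possible, adjusted p = 0.007639 over 60 measures). Antisense reads, which a coding strand alone does not give, took part in the rise. They went from 0.963 ± 0.137% of 21-nt reads in Col-0 to 16.7 ± 0.397% in the vcs sov line, and from 1.06 ± 0.0797% to 7.44 ± 0.313% with SOV present. At 22 nt the share of nuclear genes was 6.16 ± 0.981% in Col-0, 31.7 ± 4.30% in the vcs sov line, 6.18 ± 0.337% in the SOV line and 15.03 ± 1.65% in the vcs SOV line (exact permutation p = 0.002165). At 24 nt it went from 14.4 ± 1.27% in Col-0 to 16.1 ± 2.19% in the vcs sov line, and the means of the 6 vcs and 6 VCS libraries were 15.7% and 14.7% (exact permutation p = 0.229). Among nuclear-gene reads of all lengths, the 24-nt part was 33.8 ± 2.69% in Col-0 and 6.18 ± 1.49% in the vcs sov line, while the 21-nt part went from 31.2 ± 1.30% to 71.0 ± 3.76%.

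**Figure D1:**
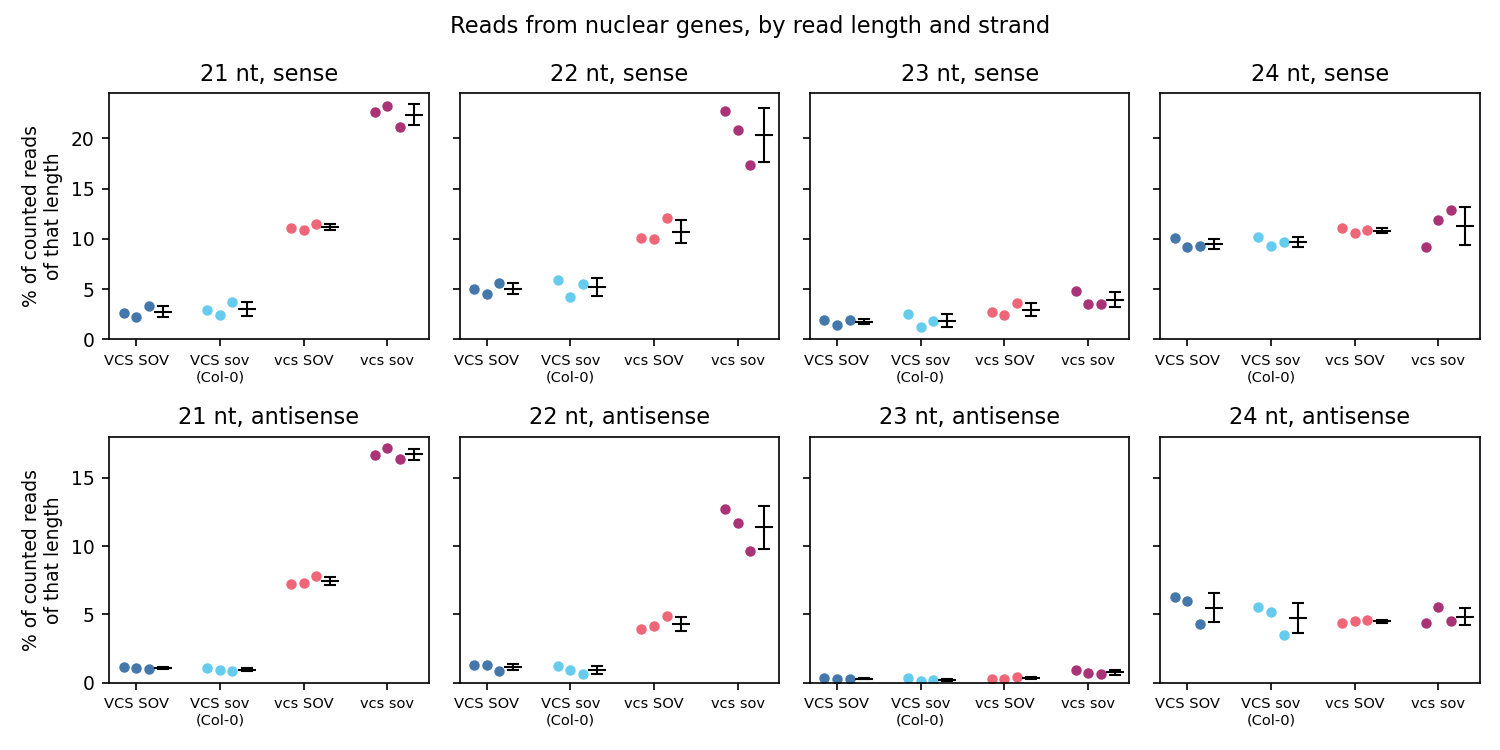
Sense (top) and antisense (bottom) reads from nuclear genes as a percent of all counted reads of each length, 21 to 24 nt, for the 4 genotypes. Points are libraries, bars the mean and SD of 3. At 21 nt, antisense reads were 16.7% in the vcs sov line, 7.44% in the vcs SOV line and near 1% in both lines with VCS.

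Other sources of 21-nt reads moved differently. Reads from TAS loci were 12.6 ± 2.70% of 21-nt reads in Col-0, 12.2 ± 0.561% in the SOV line, 7.48 ± 0.550% in the vcs SOV line and 4.64 ± 0.828% in the vcs sov line (exact permutation p = 0.002165 for 6 vcs against 6 VCS libraries). Reads from MIR genes were 31.7 ± 11.4%, 38.4 ± 11.2%, 31.5 ± 2.91% and 24.5 ± 6.12% in the same order (exact permutation p = 0.184). Cytosolic rRNA held 21.7 ± 1.49%, 19.6 ± 3.48%, 21.5 ± 1.36% and 19.0 ± 1.68% (exact permutation p = 0.777). Chloroplast rRNA held 27.3 ± 11.6%, 23.5 ± 7.07%, 18.6 ± 2.84% and 10.7 ± 5.28% (exact permutation p = 0.0433, adjusted p = 0.0764), and tRNA under 1% in each genotype. These tests ignore replicate numbers. From Col-0 to the vcs sov line, chloroplast rRNA went from 15.36, 28.26 and 38.4% to 5.725, 10.01 and 16.22% in replicates 1, 2 and 3. MIR genes went from 43.13, 31.42 and 20.4% to 30.5, 24.68 and 18.25%. Nuclear-gene reads went from 4, 3.367 and 4.565% to 39.29, 40.4 and 37.57% of the same reads, which by itself lowers other shares. A lower share here need not be a fall relative to the reads outside nuclear genes, which was not tested for these classes. With SOV present, same-numbered libraries moved both ways for both classes. At 22 nt chloroplast rRNA was lower in every vcs library than in any VCS library (means 22.2% and 35.0%, exact permutation test, adjusted p = 0.007639), and it was lower in the mean at 23 nt (68.2% and 79.6%, adjusted p = 0.0236) and 24 nt (23.6% and 31.2%, adjusted p = 0.0325). The nuclear-gene share rose at 22 nt as well, so part of the lower chloroplast rRNA share there may be dilution, which was not tested. The 10 genes that added most 21-nt reads held 19.1% of the rise from Col-0 to the vcs sov line and 18.3% of that from the SOV line to the vcs SOV line.

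**Figure D2:**
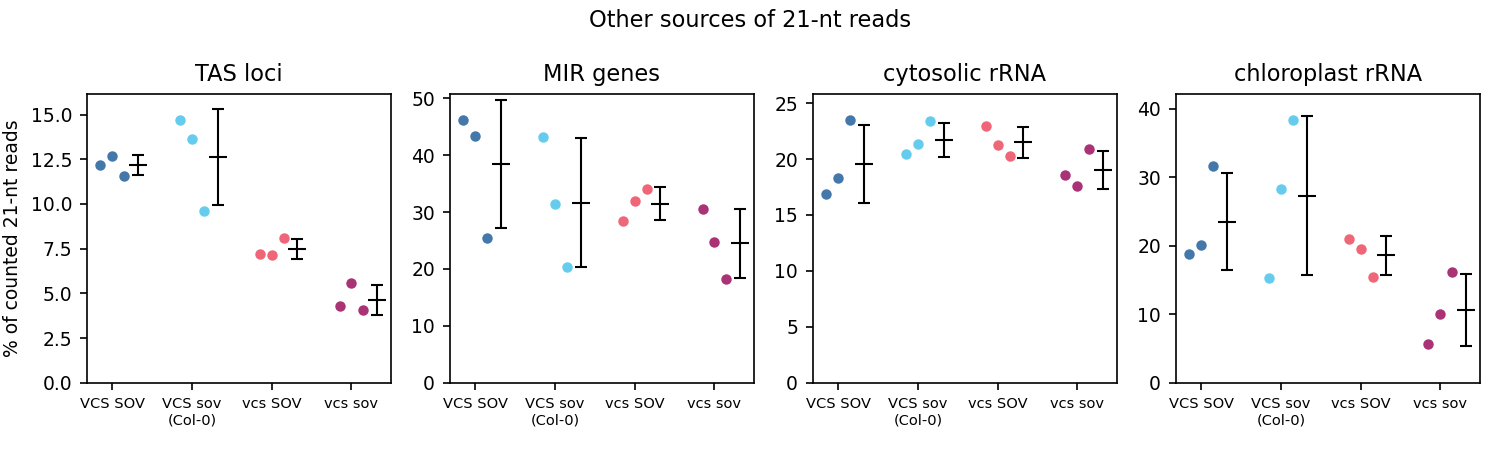
Reads from TAS loci, MIR genes, cytosolic rRNA and chloroplast rRNA as a percent of counted 21-nt reads, per library (points), with the mean and SD of 3 libraries. TAS reads averaged 12.6% and 12.2% in the lines with VCS and 7.48% and 4.64% in the vcs lines; these are shares of reads, and at this length neither MIR genes nor chloroplast rRNA passed the adjusted test, while chloroplast rRNA did at 22, 23 and 24 nt.

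The first main comparison asks what loss of VCS does where SOV is absent (vcs sov against Col-0). The 10 rises named by the rule were led by RAP2.4. Antisense 22-nt reads at RAP2.4, an AP2/ERF transcription factor of light and drought responses, rose from 8.28 ± 0.707 to 3828 ± 743 (log2 fold 8.67 ± 0.238 SE, limma adjusted p = 4.32e-13). PP2CA, a phosphatase that restrains abscisic acid signalling, had 1 sense 24-nt read in Col-0 and 1441 in the vcs sov line, a ratio of 1174 (95% interval 210.4 to 46410). Antisense 21-nt reads at PEI1, a zinc finger factor needed in embryos, rose from 14.6 ± 2.28 to 2005 ± 151 (log2 fold 7.02). KCS18, which elongates seed fatty acids, rose from 2.21 ± 1.05 to 1069 ± 280 in sense 21-nt reads (log2 fold 8.41). UGT84A2, a glucosyltransferase of sinapate metabolism, rose in antisense 22-nt reads from 6.75 ± 1.28 to 1315 ± 427 (log2 fold 7.36). The remaining 5 named by the rule were AT1G27461, AT1G22190, AT5G20700, AT1G20070 and AT2G39870, with log2 folds from 6.96 to 8.63.

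Fewer genes fell. MIR399b, whose product acts in phosphate starvation, dropped in sense 21-nt reads from 368.1 ± 204 to 15.8 ± 9.19 (log2 fold -4.41 ± 0.48 SE, adjusted p = 2.86e-07), and MIR399c fell by 4.09 on the log2 scale. LHCA2, an antenna protein of photosystem I, fell from 118 ± 13.8 to 17.2 ± 2.07 (log2 fold -2.71). Several falls were at 24 nt: MRD1, a gene named for its response in a methionine mutant, fell from 64.8 ± 26.2 to 1.70 ± 1.54 in sense reads, and the endoglucanase genes GH9B12 and GH9B9 fell in antisense reads (log2 fold -3.26 and -3.09). AT5G43755 had 54 antisense 24-nt reads in Col-0 and 0 in the vcs sov line, at least 22.1-fold lower. The other falls named by the rule were at AT1G43320, the chloroplast gene ATCG00300 and AT2G07732, and the last lost significance when values were recentred on MIR genes.

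In all, 11847 of 20590 features changed in this comparison, 9209 higher and 2638 lower, against a median log2 fold of 0.86 over all features. At 21 nt, 5606 of 7795 rose and 715 fell; at 22 nt, 2595 of 4954 rose and 534 fell. At 23 nt, 514 rose and 367 fell of 3071, and at 24 nt limma called 494 higher and 1022 lower of 4770, whereas edgeR with TMM (881 higher, 663 lower) and DESeq2 (827 higher, 522 lower) called more features higher. So did the authors' deposited table at 24 nt, over its own features (890 higher, 478 lower). Limma with library-size scaling (618 higher, 915 lower) and recentred on MIR genes (376 higher, 1065 lower) kept more falls at 24 nt. Of 4620 nuclear genes tested at 21 nt, 3497 rose on at least 1 strand, 2087 of them on both strands, and 272 fell. The filter took the mean over all 12 libraries, so features with few reads in the VCS lines entered only through high vcs values. The parts that rose are therefore parts of the features and genes tested, and not of all 27588 nuclear genes. The split depended on the test and the scaling: 77.7% of calls were higher in the main test and 87.8% with limma and library-size scaling (10697 higher, 1484 lower), against 72.8% with edgeR and DESeq2 size factors and 62.9% with edgeR and TMM (7199 higher, 4241 lower). The median of all features moved to 0.41 by edgeR with TMM, 1.38 with library-size scaling and 1.02 when recentred on MIR genes, so each fold is relative to such a shift. At 21 nt, nuclear antisense features stayed mostly higher under every scaling, with 2399 higher and 72 lower of 2625 in the main test, 2068 and 179 with TMM, and 2493 and 15 with library-size scaling. The authors' deposited table, which rests on the same size factors, called 10659 of the 11847 in the same direction and 0 in the opposite one, and edgeR with TMM 9041 and 28.

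**Figure D3:**
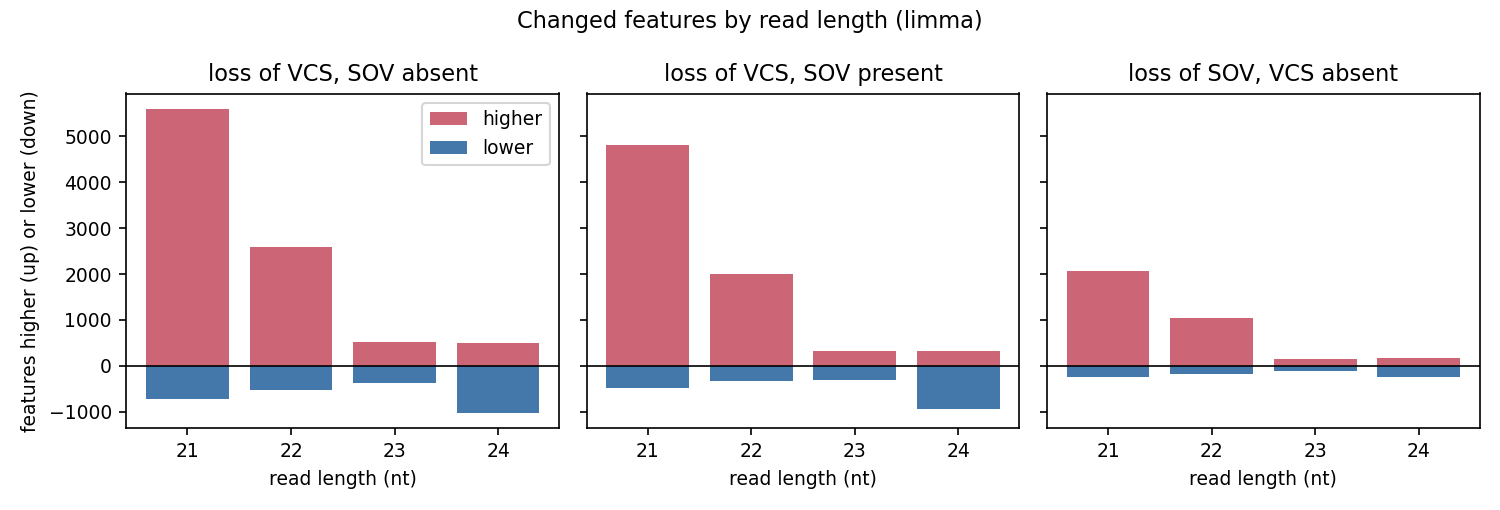
Features that rose (bars up) or fell (bars down) in the limma test, by read length, for loss of VCS without SOV, loss of VCS with SOV, and loss of SOV without VCS. At 21 nt, 5606 rose and 715 fell in the first panel and 4813 rose and 484 fell in the second; the higher share of all calls was 77.7% and 78.3%, and 62.9% and 66.7% by edgeR with TMM, and the larger number of falls at 24 nt turned into a larger number of rises under edgeR in all 3 panels.

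The second main comparison asks what loss of VCS does where SOV is present (vcs SOV against the SOV line). Genes with the strongest rises were largely those named above, joined by SMXL4 and SMXL5 (AT4G29920 and AT5G57130), relatives of strigolactone repressors that act in phloem development. Sense 21-nt reads at SMXL5 (AT5G57130) rose from 2.58 ± 1.22 to 1969 ± 262 (log2 fold 9.16 ± 0.389 SE, limma adjusted p = 4.2e-11), and those at SMXL4 (AT4G29920) from 1.52 ± 0.754 to 639 ± 25.6 (log2 fold 8.03). RAP2.4 rose from 11.03 ± 0.504 to 1119 ± 85.6 (log2 fold 6.54), UGT84A2 from 4.74 ± 1.11 to 1515 ± 186 (log2 fold 8.06), and PP2CA antisense 21-nt reads from 15.6 ± 3.55 to 2017 ± 236 (log2 fold 6.95). PEI1, KCS18, AT1G22190, AT1G20070 and AT2G39870 completed the list, with log2 folds from 5.92 to 7.17.

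Sense fragments of photosynthesis genes made up most of the strongest falls. LHCB2.1, a light-harvesting protein of photosystem II, dropped in 23-nt reads from 103 ± 26.0 to 6.90 ± 2.47 (log2 fold -3.73 ± 0.324 SE, adjusted p = 4.99e-08). LHCB6 dropped in 22-nt reads from 134 ± 14.3 to 23.8 ± 2.96 (log2 fold -2.45), and LHCB2.3 had 72 reads in the SOV line against 2 in the vcs SOV line, a ratio of 48.9 (95% interval 13.1 to 411.4). LHCB2.2, LHCB3, LHCB4.2, LHCA4, LHCA2 and PSAD-2 fell as well, with log2 folds from -3.85 to -1.76, and AT5G24250 fell by 2.94 on the log2 scale. LHCA2 lost significance when values were recentred on MIR genes, and no other of these falls did.

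Of the 20590 features 9508 changed, 7449 higher and 2059 lower, with a median log2 fold of 0.53 over all features. At 21 nt 4813 rose and 484 fell; at 22 nt 1995 rose and 325 fell; at 23 nt 329 rose and 313 fell; and at 24 nt 312 rose and 937 fell by limma, whereas library-size scaling (587 higher, 308 lower), edgeR with TMM (596 higher, 307 lower) and DESeq2 (524 higher, 227 lower) turned this balance. More falls than rises remained at 24 nt when recentred on MIR genes (314 higher, 418 lower). They remained also in the authors' deposited table, over its own features (326 higher, 584 lower). The 24-nt count of 1249 dropped to 684 without replicate 1 of the SOV line, 603 without its replicate 2 and 713 without replicate 1 of the vcs SOV line. At 23 nt the count of 642 dropped to 407 without replicate 2 of the SOV line and 414 without replicate 1 of the vcs SOV line. Of the 4620 nuclear genes that passed the filter at 21 nt, 3073 rose, 1736 on both strands, and 165 fell. The share of higher calls was 78.3%, against 75.7% with edgeR and DESeq2 size factors, 66.7% with edgeR and TMM (5352 higher, 2677 lower), 95.1% with library-size scaling (9625 higher, 496 lower) and 93.6% recentred on MIR genes (8146 higher, 555 lower). The authors' deposited table called 7810 of the 9508 in the same direction and 0 in the opposite one, and edgeR with TMM 6372 and 0.

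The vcs effects with and without SOV come from separate libraries. They had 6944 higher features in common where independent lists would share 3331.6, and 1061 lower features where 263.8 would be shared, with 17 called in opposite directions. These numbers hold among features that passed the filter on the mean of all 12 libraries, to which both vcs lines contributed. Across features, which are not independent, the fold changes correlated with r = 0.86.

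Trans-acting siRNA loci fell in both vcs comparisons. Antisense 21-nt reads at TAS1C, whose siRNAs arise after cleavage by miR173, went from 29720 ± 5741 in Col-0 to 4876 ± 945 in the vcs sov line (log2 fold -2.61 ± 0.43 SE, limma adjusted p = 3.91e-05), and at TAS4 (AT3G25795), a regulator of MYB genes, from 3376 ± 1630 to 546.2 ± 189 (log2 fold -2.54, adjusted p = 6.0e-05). With SOV, TAS4 (AT3G25795) went from 3694 ± 1360 to 661 ± 158 (log2 fold -2.43) and TAS1C sense 22-nt reads fell by 1.39. All 8 TAS loci were measured: without SOV 6 fell, 2 did not change and none rose (34 of 53 features lower, 35 adjusted over the list alone), and with SOV 7 fell and 1 did not change (34 features, 36 adjusted over the list alone). The 34 with SOV dropped to 18 without replicate 1 of the SOV line and 16 without its replicate 2. At 21 nt the median log2 fold was -1.91 and -1.46, camera adjusted p = 1.13e-14 and 1.44e-13, but adjusted p = 0.147 and 0.145 with an estimated correlation. Camera compares a list with the other features, and the median of all 21-nt features was 2.79 and 1.84. It can therefore place a list lower that did not fall, here and for the lists below. The fry test gave adjusted p = 0.00269 and 0.0101 at 21 nt, but 0.0671 and 0.0551 at 22 nt. TAS features stayed lower in the median under every scaling tried for these comparisons, with the 21-nt calls without SOV going from 12 of 15 lower to 15 with TMM and 4 with library-size scaling.

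Coding genes prone to gene silencing in decay mutants gained small RNAs. At NIA1, a nitrate reductase gene, antisense 21-nt reads rose from 12.5 ± 4.93 in Col-0 to 1027 ± 78.0 in the vcs sov line (log2 fold 6.31 ± 0.314 SE, limma adjusted p = 5.11e-11) and from 7.10 ± 0.12 in the SOV line to 171 ± 33.1 in the vcs SOV line (log2 fold 4.39). SMXL5 (AT5G57130) rose without SOV too, from 4.18 ± 1.92 to 251 ± 81.4 (log2 fold 5.63). Its level in the vcs SOV line, 1969 ± 262, was higher than in the vcs sov line (log2 fold -3.02, adjusted p = 4.37e-05). All 4 members of this list were measured. Without SOV 3 rose, while NIA2 rose in some features and fell in 2 of 23 or 24 nt, among them sense 24-nt reads. Of the list's 27 features 20 were higher and 2 lower, likewise 20 and 2 adjusted over the list alone. With SOV all 4 rose (23 features higher, 23 adjusted over the list alone). Camera gave adjusted p = 0.0384 without and 0.000656 with SOV, and adjusted p = 0.147 and 0.0551 with an estimated correlation; fry gave 3.13e-08 and 1.44e-08. The rise held under every scaling, with 19 features higher and 3 lower under TMM without SOV.

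**Figure D4:**
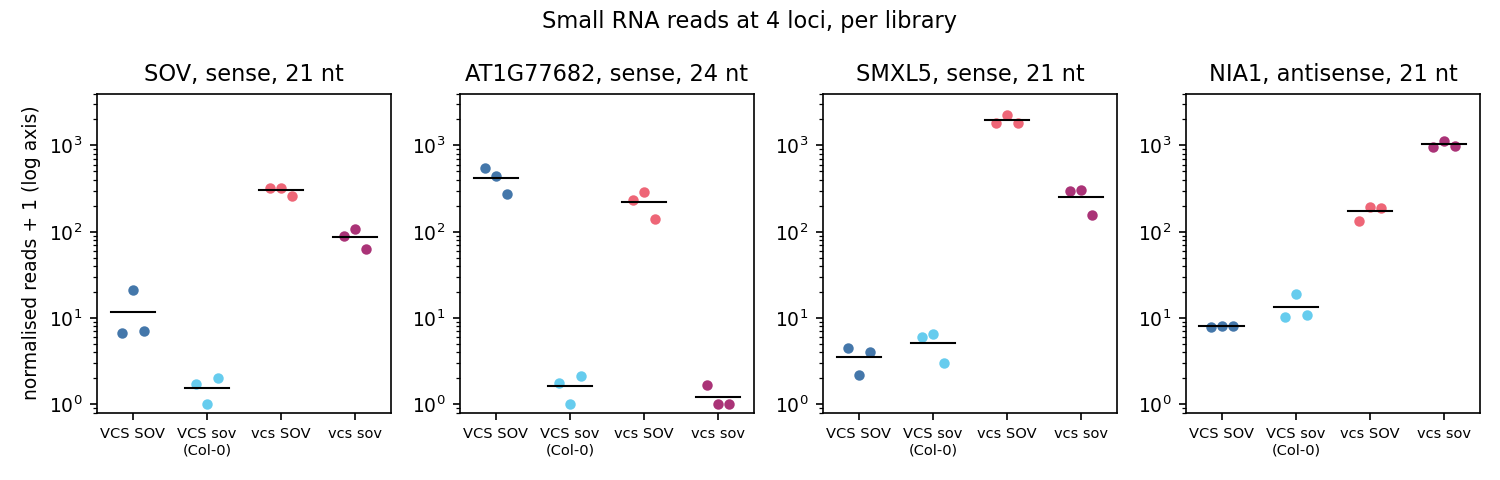
Normalised reads plus 1, on a log axis, at SOV (sense, 21 nt), its neighbour AT1G77682 (sense, 24 nt), SMXL5 (sense, 21 nt) and NIA1 (antisense, 21 nt), with 1 point per library and a line at the mean of 3. SMXL5 is highest in the vcs SOV line (1969), NIA1 in the vcs sov line (1027), and AT1G77682 is near 0 in both lines without SOV.

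The auxin receptors gained reads at all 3 measured members of 4. TIR1 rose in sense 21-nt reads from 7.01 ± 1.34 to 79.6 ± 15.9 without SOV (log2 fold 3.32, limma adjusted p = 1.04e-07) and from 6.31 ± 0.738 to 54.5 ± 8.85 with SOV (log2 fold 2.92), and AFB2 rose by 4.39 and 4.57 on the log2 scale in antisense 22-nt reads. Of 17 features 15 rose without SOV and 14 with SOV (16 and 15 adjusted over the list alone), under every scaling tried. At 21 nt, where features in general rose, camera set them apart in neither comparison (adjusted p = 0.344 and 0.11, adjusted p = 0.599 and 0.437 with an estimated correlation). At 22 nt it placed them higher with SOV (adjusted p = 0.0336, adjusted p = 0.182 with an estimated correlation) and not without (0.112).

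The decay machinery list behaved alike, with 6 of 13 members measured and 5 higher in both vcs comparisons (13 of 19 features, 13 adjusted over the list alone). SOV (AT1G77680), whose allele differs between the lines, supplied 6 of the 13. DCP2, the decapping enzyme, had 0 antisense 21-nt reads in Col-0 and in the SOV line, 29.1 ± 3.92 in the vcs sov line and 3.75 ± 2.17 in the vcs SOV line. LSM1B and PAT1 (AT1G79090), activators of decapping, rose too, and VCS itself did not change. Camera gave adjusted p = 0.115 without and 0.0996 with SOV, and adjusted p = 0.207 and 0.225 with an estimated correlation. With TMM, 1 feature of the list fell with SOV. Of 11 small RNA pathway genes only DCL4, a Dicer that makes 21-nt siRNAs, had a feature to test: its antisense 24-nt reads fell from 10.4 ± 5.22 to 1.37 ± 1.18 without SOV (adjusted p = 0.00184) and from 21.1 ± 7.49 to 3.85 ± 1.74 with SOV (adjusted p = 0.00437), 1 feature in each also adjusted over the list alone.

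For PPR genes, targets of TAS1 and TAS2 siRNAs, the direction depended on scaling. Antisense 21-nt reads at AT1G62590 fell from 74.7 ± 18.3 to 28.7 ± 2.81 without SOV (log2 fold -1.32, limma adjusted p = 0.00254). Of 15 members 14 were measured; without SOV 12 fell, 2 did not change and none rose (21 of 76 features, 3 adjusted over the list alone), and with SOV 2 fell (2 features, 0 adjusted over the list alone by limma). The 21 became 8 without replicate 1 of Col-0, and 5 without its replicate 2 or without replicate 3 of the vcs sov line. The 2 became 13 without replicate 3 of the SOV line, and 1 without replicate 1 or 2 of the SOV line or of the vcs SOV line. Camera gave adjusted p = 4.78e-17 and 4.74e-11, but adjusted p = 0.147 and 0.225 with an estimated correlation. The fry test gave adjusted p = 0.0445 and 0.279 at 21 nt, and 0.466 and 0.469 at 22 nt. With library-size scaling, 4 PPR features rose and none fell without SOV, and the list's median turned positive in both comparisons.

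MIR genes fell on balance with the deposited scaling, while with library-size scaling the median without SOV turned positive (0.25), with 17 features higher and 10 lower. Of 41 listed MIR genes 38 were measured. Without SOV 16 fell, 4 rose, 1 did both and 17 did not change (5 features higher and 23 lower of 96, 3 and 16 adjusted over the list alone). With SOV 19 fell, 1 rose, 1 did both and 17 did not change (2 higher and 27 lower, 2 and 20 adjusted over the list alone). Besides MIR399b, MIR319a, whose product restrains leaf growth factors, fell without SOV in sense 22-nt reads (log2 fold -2.07), and MIR172a, a timer of development, fell with SOV from 70.6 ± 34.7 to 6.47 ± 5.58. Camera gave adjusted p = 1.97e-17 and 1.17e-20, but adjusted p = 0.147 and 0.145 with an estimated correlation. The fry test did not call the MIR list, with adjusted p = 0.0681 and 0.0657 at 21 nt and 0.554 and 0.15 at 22 nt. The 28 calls without SOV became 44 without replicate 3 of Col-0. The 29 with SOV became 14 without replicate 1 or replicate 2 of the SOV line, 16 without replicate 1 of the vcs SOV line and 50 without replicate 3 of the SOV line.

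Among other miRNA targets, 12 of 32 were measured. Without SOV 6 rose, 1 fell and 5 did not change (8 features higher and 2 lower of 28, likewise 8 and 2 adjusted over the list alone); with SOV 3 rose, 1 fell and 8 did not change (5 higher and 2 lower, 4 and 2 adjusted over the list alone). The one that fell was AGO2, an Argonaute targeted by miR403, from 384.5 ± 127 to 141 ± 63.3 in antisense 21-nt reads without SOV (limma adjusted p = 0.00254). TOE1 (AT2G28550), a repressor of flowering, rose in both comparisons and PHO2, a regulator of phosphate uptake, rose without SOV. The list's median and mean at 21 nt were positive (0.89 and 0.85 without SOV) while camera placed it below other features (adjusted p = 0.0122, adjusted p = 0.242 with an estimated correlation; with SOV 0.0358 and 0.372). At 22 nt camera did not call it (adjusted p = 0.145 and 0.0771). The 7 calls with SOV became 4 without replicate 2 of the SOV line. Of 9 NB-LRR genes, immune receptors with secondary siRNAs, 5 were measured. AT5G43740 fell without SOV (395.9 ± 150 to 155 ± 43.0, adjusted p = 0.00583; 1 of 15 features, 1 adjusted over the list alone; camera adjusted p = 0.000223 at 21 nt, adjusted p = 0.207 with an estimated correlation, and 0.227 at 22 nt). The falls were 2 without replicate 3 of the SOV line, 3 without replicate 3 of Col-0 and 2 with a replicate block, and without replicate 1 of Col-0 there were 1 fall and 1 rise. No NB-LRR feature passed with SOV by limma (0, also adjusted over the list alone; camera adjusted p = 0.109, adjusted p = 0.517 with an estimated correlation), and leaving out single libraries gave up to 3 calls in mixed directions: 3 rises without replicate 2 of the SOV line, 1 rise without replicate 2 or 3 of Col-0, 1 fall without replicate 2 of the vcs sov line or replicate 1 of the vcs SOV line, and 1 of each without replicate 3 of the vcs sov line. At 21 nt their median was negative without SOV (-0.27) and positive with SOV (0.48), where camera still pointed down. The fry test called the NB-LRR list in neither comparison at 21 nt (adjusted p = 0.404 and 0.301).

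Where VCS is present, loss of SOV (Col-0 against the SOV line) changed few features, most of them at 24 nt. Sense 24-nt reads at AT1G77682, the annotated neighbour of SOV, numbered 940 in the SOV line and 2 in Col-0, a ratio of 573.7 (95% interval 158.4 to 4744; limma adjusted p = 1.09e-10). The same locus had 553 reads in the vcs SOV line and 1 in the vcs sov line, a ratio of 683 (95% interval 122 to 27040). Antisense 24-nt reads at RD20, a caleosin induced by dehydration, were 39.4 ± 14.4 in the SOV line and 0 in Col-0, at least 35.8-fold lower. AT3G23633 was at least 22.4-fold lower, AT3G53065 had a ratio of 28.7 (95% interval 7.51 to 243.8), and AT3G22770 fell from 31.0 ± 14.3 to 1.16 ± 1.18. Higher in Col-0 were antisense reads at AT2G01008 (22 nt, 19.5 ± 5.38 to 103 ± 46.2, adjusted p = 0.0119) and AT4G12820 (24 nt, 3.67 ± 2.30 to 36.8 ± 14.4, adjusted p = 0.0372), and sense reads at AT4G02715, AT5G26700 and EIF2 BETA (at least 2.85-fold, 13.7-fold and 3.71-fold higher).

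In total 36 features changed, 5 higher and 31 lower, among 1706 with an unadjusted p under 0.05. At 24 nt 25 fell, at 18 genes. DESeq2 on the recovered reads called 32, edgeR with TMM 31 and the authors' deposited table called 33 of the features tested here, of which 27 were among the 36 with the same direction. The count was 13 without replicate 1 or without replicate 2 of the SOV line. With values recentred on MIR genes 5 of 13 calls were higher, against 5 of 36 in the main test. Every one of the 5 higher genes lost its call under several alternatives, AT4G02715 under 16 of 23 and EIF2 BETA under 18 of 22. AT1G77682, AT3G23633, RD20 and AT3G22770 kept theirs under all that tested them. Of the gene lists only the decay machinery had calls, 2 lower features at SOV itself (5 adjusted over the list alone). The share of nuclear genes among 21-nt reads differed by 0.166 percentage points between these genotypes (exact permutation p = 0.7, where 0.1 is the smallest possible).

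Where VCS is absent, loss of SOV (vcs sov against vcs SOV) changed more features. The 2 counts are not like for like, since many tested features had few reads where VCS is present. Gene strands with any 21-nt read numbered 15370 to 19956 per library with VCS and 28604 to 42469 per vcs library. An effect of SOV at features near 0 in the lines with VCS could not be seen. Sense 21-nt reads at SAG29, a sugar transporter of senescence and seeds, were absent from the other 3 genotypes and reached 34.0 ± 12.3 in the vcs sov line, at least 53.3-fold higher than in the vcs SOV line. TSPO, a membrane protein induced by abscisic acid, went from 2 to 461 reads, a ratio of 110.7 (95% interval 30.5 to 917). LEA4-5, a protein of desiccating seeds, rose from 3.76 ± 0.918 to 105 ± 10.6 (log2 fold 4.49 ± 0.365 SE, limma adjusted p = 1.05e-06). NPY4 was at least 35.1-fold higher and AT5G56520 rose from 1.06 ± 0.224 to 20.3 ± 5.97. Besides AT1G77682, lower genes were AK3, an aspartate kinase (antisense 21-nt reads, 119.8 ± 26.7 to 7.66 ± 3.85, adjusted p = 1.01e-05), AT1G73650 (antisense 24-nt reads, 1312 ± 450 to 173 ± 28.0), MRD1 and MIR169e (log2 fold -3.79 and -3.78).

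Here 4212 features changed, 3423 higher and 789 lower (2058 and 252 at 21 nt, 1035 and 176 at 22 nt, 157 and 109 at 23 nt, 173 and 252 at 24 nt, where edgeR with TMM called 367 and 249), with a median log2 fold of 0.32. At 24 nt library-size scaling kept more falls (173 higher, 550 lower), while recentring on MIR genes did not (192 higher, 158 lower). The split over all lengths depended on the test and on the scaling: by limma 81.3% were higher in the main test and 95.1% recentred on MIR genes (5251 higher, 271 lower). On recovered reads with DESeq2 size factors it was 69.8% by edgeR (3876 higher, 1680 lower) and 69.0% by DESeq2 (3575 higher, 1609 lower), and with TMM 54.8% by edgeR (2971 higher, 2453 lower). Without replicate 1 of the vcs sov line 2576 features changed, and 2635 without its replicate 2. As shares of reads, nuclear genes held 20.5 percentage points more of the 21-nt reads in the vcs sov line than in the vcs SOV line, with no overlap of libraries (exact permutation p = 0.1, the smallest possible for 3 against 3). In the silencing-prone list, NIA1 antisense 21-nt reads rose (log2 fold 2.60, adjusted p = 2.93e-05) while SMXL5 (AT5G57130) and SMXL4 (AT4G29920) fell (log2 fold -3.02 and -2.69), with 6 features higher and 13 lower of 27 (7 and 16 adjusted over the list alone; camera adjusted p = 0.000976, adjusted p = 0.0756 with an estimated correlation). In the NB-LRR list 2 members fell (3 features, 4 adjusted over the list alone). Camera placed the list lower at 21 nt (adjusted p = 8.66e-07, adjusted p = 0.219 with an estimated correlation). The fry test called neither the NB-LRR list nor the silencing-prone list here at 21 nt (adjusted p = 0.102 and 0.0835). TAS loci had 1 feature higher and 4 lower, PPR genes 0 and 3, and MIR genes 1 and 6. Adjusted over each list alone, these were 0 and 0, 0 and 0, and 1 and 4.

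Loss of both activities (vcs sov against the SOV line) changed 13294 features, 9474 higher and 3820 lower; with TMM it was 7348 higher and 4532 lower, and with library-size scaling 11133 and 1977. The named rises were RAP2.4, AT1G27461, PP2CA, PEI1 and AT1G22190, and the named falls AT1G77682 (940 reads against 1), MRD1, GH9B12, GH9B9 and AT5G43755 (at least 42.4-fold lower). The cross comparison (vcs SOV against Col-0) changed 7941 features, 7162 higher and 779 lower; with TMM it was 5396 higher and 2286 lower. Its named rises were RAP2.4, PEI1, UGT84A2, SMXL5 (AT5G57130) and KCS18, and its named falls LHCB2.1, LHCB2.2, LHCB6, LHCB3 and AT5G24250.

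The interaction asks whether the vcs effect differs with SOV. WRI1, a regulator of seed oil synthesis, rose in sense 21-nt reads from 0 in Col-0 to 157 ± 37.4 in the vcs sov line, but from 2.30 ± 1.23 in the SOV line to 7.13 ± 2.59 in the vcs SOV line (limma adjusted p = 8.2e-05). SAG29, TSPO, NPY4 and AT5G56520 had reads mainly in the vcs sov line. The opposite held for SMXL5 (AT5G57130; log2 interaction -3.54 ± 0.549 SE, adjusted p = 0.00132), AK3, and GER3, a germin-like protein whose sense 23-nt reads went from 11.6 ± 1.90 to 9.61 ± 2.39 without SOV and from 5.34 ± 5.57 to 70.1 ± 20.8 with SOV. RBCS1B, a small subunit of Rubisco, fell only without SOV (128.5 ± 24.3 to 38.1 ± 14.7), and MRD1 fell more without SOV (log2 interaction -3.37). AK3, SMXL5 (AT5G57130), GER3, WRI1, TSPO and MRD1 kept their calls under every alternative that tested them, while SAG29, NPY4, AT5G56520 and RBCS1B lost theirs under some.

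By limma 1867 features differed, 1687 upward and 180 downward. Number and direction differed between limma and the tests on counts. Limma also called mostly upward features with library-size scaling (3275 upward and 242 downward of 3517) and recentred on MIR genes (302 and 31 of 333). On recovered reads, edgeR with DESeq2 size factors called 388 (188 upward, 200 downward), DESeq2 620 (297 and 323) and edgeR with TMM 499 (138 and 361). The median log2 interaction of 21-nt features was 0.72 in the main test, 0.18 with edgeR and DESeq2 size factors and -0.06 with edgeR and TMM. Without replicate 1 of the vcs sov line the count was 908, and without its replicate 2 it was 999. The silencing-prone list differed from other 21-nt features in this contrast (camera adjusted p = 0.000632, adjusted p = 0.0488 with an estimated correlation). At 22 nt the call was lost with an estimated correlation (camera adjusted p = 0.00421, adjusted p = 0.133 with an estimated correlation). Over all lengths 3 of its 27 features went upward and 8 downward (5 and 14 adjusted over the list alone).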

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

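Of the tests of the rise of nuclear-gene reads, those of RNA breakdown and of library depth were chosen after the result was seen, and that of a few genes before. Nuclear-gene reads of 21 nt are a larger share in the vcs lines. If breakdown of RNA alone made these reads, their antisense part would be no higher in the vcs lines, yet it was higher by 14.93 percentage points. It was 39.4 to 43.6% per vcs library and 18.2 to 32.1% per library with VCS. Breakdown into sense fragments alone would not give the added antisense reads. The reads were still mostly sense, so the test cannot exclude breakdown as a source of the added sense reads. If library depth made the difference, shallow vcs libraries would lack it, yet the shallowest, with 4.18 M reads, had 18.32% of its 21-nt reads from nuclear genes, above the 4.57% of the highest library with VCS. If a few genes carried the rise, the top 10 would hold most of it, but they held 19.05%. A hypothesis, not tested here, is that transcripts left undegraded without VCS may enter small RNA production, which mRNA levels and cap status in the same seedlings would test.

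The test of dilution was chosen after the fall of TAS reads was seen. TAS reads are a smaller share of 21-nt reads in the vcs lines, and the added nuclear-gene reads alone could lower that share. Among 21-nt reads outside nuclear genes, TAS loci still held less in the vcs lines, 8.417 ± 1.37% against 12.9 ± 1.8% (exact permutation p = 0.004329, n = 6 each). The highest vcs library (10.06%, vcs SOV replicate 3) and the lowest VCS library (10.04%, Col-0 replicate 3) overlapped, so the rule set for this test gave no decision. These 2 libraries differ in SOV status, and within each SOV background every vcs library lay below every VCS library. The values argue against dilution by nuclear-gene reads as the whole cause of the smaller share. Part of it may still be dilution, and shares do not give absolute amounts.

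The test of a linked stretch was chosen before its result was seen. The 24-nt features lower without SOV where VCS is present could come from 1 stretch of the genome that differs between the lines, since the SOV allele came from another accession. No run of 200 neighbouring genes held more than 2 of the 18 genes, 11.11%, so a single stretch does not account for most of them. Some genes do lie as close pairs, such as AT5G44830 and AT5G44840, and several separate stretches were not tested. Whether the lines carry the SOV allele as a transgene or as an introgressed segment is not clear from the labels, so differences at genes near SOV, such as AT1G77682 and NIA1 (AT1G77760), may reflect the segment rather than SOV activity.

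The count of each of the 6 direct comparisons was larger than in any other of the 10 splits of its libraries, so 1 split of 10, the real one, reached it. That many splits are too few to give a share under 0.05. Real counts and the highest other were 11847 and 0, 9508 and 0, 36 and 3, 4212 and 0, 13294 and 0, and 7941 and 0, in the order vcs without SOV, vcs with SOV, SOV with VCS, SOV without VCS, double loss and cross comparison. For the interaction 3 of 100 splits reached the real count of 1867, and the highest other was 3039.

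The vcs effect differed with SOV for 1867 features by limma. Log2 interactions of the named genes were as follows, where values of genes with 0 to 3 reads in a group depend on the pseudocount and are no bound. RAP2.4 had 2.133, AT1G27461 2.764, PP2CA 4.284, AT1G22190 1.516 and AT5G20700 3.555. Among genes that fell without SOV, MRD1 had -3.369, GH9B12 -2.15, GH9B9 -1.797, AT1G43320 -1.775, AT2G07732 -1.421 and AT5G43755 -2.992. SMXL5 (AT5G57130) had -3.536 and SMXL4 (AT4G29920) -2.74, while LHCB2.1 had 2.167 and LHCB2.2 2.046. Of genes named for the interaction itself or for SOV, SAG29 had 5.057, TSPO 5.891, NPY4 4.713, WRI1 5.952 and AT5G56520 3.335, and AK3 had -3.809, GER3 -4.071 and RBCS1B -2.211.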

How the results depend on the processing

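Leaving out 1 library at a time moved the counts within these ranges: vcs without SOV 10812 to 12154, vcs with SOV 7847 to 9908, SOV with VCS 13 (without replicate 1 of the SOV line) to 51 (without its replicate 3), SOV without VCS 2576 (without replicate 1 of the vcs sov line) to 4553 (without replicate 3 of Col-0), double loss 11996 to 13570, cross comparison 6951 to 8196, interaction 908 (without replicate 1 of the vcs sov line) to 1944 (without its replicate 3), 21-nt features changed by vcs without SOV 5954 to 6399, and list features 112 to 173. The cause of these moves was not tested, beyond the smaller number of libraries.

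With a mean of 10 or more, fewer features were tested and the counts were 6666, 5541, 23, 2677, 7608, 4431 and 1202 in the order vcs without SOV, vcs with SOV, SOV with VCS, SOV without VCS, double loss, cross and interaction, with 3407 at 21 nt (the size classes result, vcs without SOV). Without a filter more features were tested and the counts were 36483 for vcs without SOV, 8367 for SOV without VCS, 38943 for the double loss, 12938 for the cross comparison and 476 for the interaction, with 19838 for size classes. At an adjusted p of 0.01, which is stricter by construction, 18 features changed with SOV loss where VCS is present, 2290 where it is absent, and 633 in the interaction. Per 1e+06 counted reads, SOV loss without VCS changed 6699. Recentred on MIR genes, SOV loss with VCS changed 13.

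The interaction count also depended on the test and the scaling, against 1867 in the main test: 388 with edgeR and DESeq2 size factors, 620 with DESeq2, 499 with edgeR and TMM, 1078 and 3835 with pseudocounts of 0.5 and 5, 3517 per 1e+06 counted reads and 333 recentred on MIR genes. The cause was not tested. Settings chosen after the data were seen were both pseudocounts, both further scalings, the filter of a total above 0, shares among reads other than rRNA and the removal of the 4 libraries numbered 3. EdgeR with TMM was the test the design foresaw for raw counts. It became an alternative, on the recovered reads, when limma was made the main test.

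A replicate block gave 12514, 10478, 49, 4937, 13849, 8583 and 2282 in the same order. Over all groups 6 of 18 same-numbered pairs had a correlation over 0.1, from -0.0536 to 0.281, and in 13 of 18 the best match had the same number, a hint from the data and not the design. All 3 pairs were over 0.1 only between Col-0 and the vcs sov line. There the block changed no camera call and no call of a named gene; by fry, other miRNA targets (higher, adjusted p = 0.0136 from 0.0681) and MIR genes (lower, 0.0425 from 0.0681) passed with it. Without the 4 libraries numbered 3 the counts were 11806, 9847, 31, 3618, 13116, 8126 and 1287. Among reads other than rRNA, the difference in the 21-nt nuclear share between vcs and VCS lines was 36.0 percentage points against 24.95 among all.

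Of other results, leaving out a library moved 36 (15 larger, 21 smaller), ended 35 calls and left 1381 alike, and other settings moved 98 (52 larger, 46 smaller), ended 31 and left 1225 alike. All 90 named features kept their sign in every alternative, and 78 kept their call. Tests foreseen and not run, because the files hold gene totals with reads, were a limit to 20 to 24 nt, counts of single sequences and their positions, exact mature miRNA sequences, and tests meant for a table of the authors' results alone.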

Other observations

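At 21 nt, where 5606 of all 7795 features rose without SOV, some groups formed from gene descriptions had few features that did not rise. Zinc finger genes had 162 of 170 features higher and 0 lower without SOV by limma, WRKY genes, which act in defence, 15 of 15, AP2/ERF genes 30 of 32 and MYB genes 44 of 47. Expansins, which loosen cell walls, had 14 of 15 higher, with a median log2 fold of 4.90, and aquaporins 30 of 32. Tested were only 102 of 504 zinc finger, 8 of 72 WRKY and 18 of 89 AP2/ERF genes. Of MYB, expansin and aquaporin genes, 25 of 153, 9 of 34 and 19 of 37 were tested. A gene can give a feature on each strand, and nothing was tested for the other members. With SOV the same groups had 157, 14, 28, 47, 14 and 25 features higher. Relative to other 21-nt features camera placed all 6 groups higher without SOV. The camera adjusted p was 6.68e-06 for zinc finger, 0.00137 for MYB, 0.0184 for WRKY and 0.00486 for AP2/ERF genes. It was 0.00572 for expansins, 0.00486 for aquaporins and, outside these groups, 0.0156 for histones. None of these calls held with an estimated correlation, where camera gave adjusted p = 0.38 for each of the 6 groups and for histones. Protein kinases and ribosomal proteins had median log2 folds of 2.87 and 2.52 against 2.79 for all 21-nt features without SOV. Camera placed kinases slightly higher (adjusted p = 0.0396) and did not call ribosomal proteins (0.0689), with adjusted p = 0.618 for both with an estimated correlation.

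Several groups took little part in this rise. Without SOV, pentatricopeptide repeat proteins had 7 features higher and 11 lower (median log2 fold -0.56), disease resistance proteins 16 and 6 (0.04) and peroxidases 6 and 4 (0.50), which camera placed below other features (adjusted p = 1.05e-08, 8.21e-06 and 0.0136) but not with an estimated correlation (adjusted p = 0.38, 0.388 and 0.38). Light-harvesting and photosystem genes kept their call. Of the 66 light-harvesting and photosystem features at 21 nt, 21 rose and 34 fell without SOV, and 19 rose and 26 fell with SOV, the median log2 fold being -0.81 and -0.46, while library-size scaling turned both medians positive (0.57 and 0.47). Relative to other 21-nt features they were lower by camera (adjusted p = 1.56e-12 and 1.14e-11, adjusted p = 0.0299 and 0.0373 with an estimated correlation). Reads from chloroplast genes fell with them in the main test, with 275 of 554 features of all lengths lower and none higher without SOV and 167 lower and none higher with SOV; at 21 nt library-size scaling (0.06 without SOV) and recentring on MIR genes (0.16 without and 0.03 with SOV) turned their median positive. At 24 nt 27 of the 42 light-harvesting and photosystem features fell and none rose without SOV, and 17 fell with SOV; with TMM these were 18 and 7.

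A hypothesis, not tested here, is that sense fragments of abundant photosynthesis transcripts arise by decay that needs VCS, and may be replaced by siRNAs at other genes. It does not address the reads from chloroplast genes, which fell too in the main test. Differences in the make-up of the whole seedlings were not measured. LHCB2.1 kept its fall in every alternative tried (log2 fold -3.97 to -3.17 with SOV). Degradome sequencing of 5′ ends and mRNA levels of the same seedlings would test it, and small RNA of vcs lines that also lack RDR6 would test whether the antisense reads depend on that polymerase.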
